A study of Mus musculus with 16 samples.

How the data were processed

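The series holds 16 mouse RNA-seq libraries in 8 groups of 2, one group for each combination of stage (E9.5, E10.5), site (embryo region, yolk sac) and sorted cell type (EC, HE), as given by the labels. Conceptuses came from superovulated B6C3F1 females mated with males homozygous for a Runx1-GFP allele. Tissue was digested with collagenase and stained for CD31, CD41, CD45 and kit, per the labels' protocols. Cells were sorted into Trizol-LS or into a serum buffer, and RNA was cleaned with a column kit and DNase treatment on the column or in solution. Which library received which treatment is not given in the sources used here, so these steps could not be tested as batches. The labels do not say that the replicates are separate litters or sorts, so p-values measure only the spread between these samples, which may be technical.

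The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) computed by the authors and deposited as 1 table of 33531 gene symbols by 16 libraries. Cufflinks and featureCounts are named without version or role per the submitters' processing notes, together with the genome build mm9. The aligner, the gene annotation, the treatment of reads that match several places and the use of strand are not given in the sources used here. The values were used as deposited, with no further scaling in the main fit. An mm9 annotation was not used here, so genes are given by symbol without coordinates. Because FPKM depends on the other transcripts of a library, a few abundant genes can shift all others, and genes that share sequence with copies elsewhere (pseudogenes, globin genes) carry uncertain values. Zeros can stand for missing estimates: 45 tested genes, Col1a1, Igf2 and Mest among them, were listed at 0 in some library while at least 8 others were above 0 and none of these was under 3 FPKM. Such genes are given by library, and where a fitted value or call of Col1a1 is given, it rests on these zeros unless the libraries that hold them were left out.

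Depth is unknown in reads. Below an FPKM of 0.3 the values of a gene lie on steps whose size depends on the gene and the library, and these steps were compared between libraries to estimate relative depth, accepted where the best ratio scored at least 1.5 times the next. Of 15 libraries compared with 1 other, 11 had a clear step, at 0.71 to 1.1 times its reads, and 4 had none. The sum of FPKM lay between 586501 and 785252, the genes with an FPKM of at least 1 between 11639 and 12527, and the share of genes at 0 between 45.6% and 54.3%.

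Genes with an FPKM of at least 1 in at least 2 libraries were tested, 13955 in all, and 19576 were not tested. Values were transformed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. A model with 1 mean per group was fitted to all 16 libraries with limma 3.58.1 in R 4.3.3 (residual degrees of freedom 8, prior degrees of freedom 3.68, intensity trend), so that the groups share 1 estimate of the spread. From it 11 comparisons were taken: HE against EC over all settings and within each stage and site, yolk sac against embryo within HE and within EC, E10.5 against E9.5 within HE and within EC, and the interactions of cell type with site and with stage. Contrasts over several settings average the settings equally. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Changes in both directions were tested.

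Gene groups came from 28 lists: sort markers; general, arterial, venous and sinusoidal or lymphatic endothelium; blood transcription factors; general blood cells; erythroid, megakaryocyte and macrophage cells; mesenchyme and somite; neural cells; visceral endoderm and epithelium; cell cycle; Notch, BMP and TGF-β, Wnt, interferon and retinoic acid genes; Hox genes; flow response; basement membrane; glycolysis; cholesterol synthesis; the let-7 and Lin28 axis; imprinted growth genes; dissociation response; and sex-linked genes. The 27 lists with at least 5 tested members were compared with all other genes by limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move on balance in one direction. Of the calls by camera, only the macrophage list in both stage comparisons held with an estimated correlation, and its called genes had means under 1 FPKM at E9.5. Counts adjusted over the list alone apply the adjustment to the members of that list.

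Groups, comparisons, tests, lists, the naming rule and most of the other settings tried were fixed before the data were examined. The rule named, among called genes with a mean FPKM of at least 5 in the higher group and the same direction in every setting, the 8 largest rises and 8 largest falls for HE against EC over all settings and for site and stage in HE. It named 4 of each in the other comparisons, and in the interactions genes with at least 5 FPKM in some group. It added up to 4 called and 2 uncalled members of each list and the 5 sort markers, and it left unnamed gene models and small RNA genes counted without a name. Genes outside the rule are marked in the text as named after their values were seen. Of the genes that the rule named, 1 is not reported here.

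Settings chosen in advance were pseudocounts of 0.1 and 5, no filter, a filter at FPKM 5, median-of-ratios scaling, quantile normalization, no intensity trend, robust empirical Bayes, library quality weights, small RNA genes left out, the replicate number as a block, only the libraries of the groups compared, and each library left out in turn. When a library was left out, the lone library of its group was assumed to vary like the other groups. The lists were also run with a pseudocount of 0.1, median-of-ratios scaling and the replicate block. Added after the data were seen were the runs without both libraries labelled HE of the E10.5 yolk sac, without both E10.5 yolk sac libraries numbered 1, without the 45 genes listed at 0, and without unnamed models, pseudogenes and small RNA genes.

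The fit was tested on simulated data with the spread and means of the 13955 genes. At log2 changes of 0.5, 1 and 2 it recovered 47.8%, 92.5% and 97% of changed genes for HE against EC over all settings, with 7 unchanged genes called. For yolk sac against embryo in HE it recovered 25.4%, 85.1% and 95.5%, with 5 unchanged genes called, and for HE against EC in the E9.5 embryo 7.46%, 43.3% and 90.9%, with 3. Changed genes were drawn from the more abundant genes only, so these rates do not cover low genes. A shifted list was called in each of these comparisons and 0 of 19 unchanged lists was. Simulated genes varied independently, whereas the general endothelial list had an estimated correlation of 0.88. This check therefore could not show false list calls that arise from correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.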

Results

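RNA was measured in endothelial cells and in hemogenic endothelium, the endothelial cells from which blood cells bud, sorted from mouse conceptuses that carried a Runx1-GFP reporter. Endothelial cells (EC) were sorted as GFP-negative, CD31-positive and kit-negative, and hemogenic endothelial cells (HE) as GFP-positive and CD31-positive with low or no kit. Both gates excluded cells with CD41 or CD45 on their surface. Each cell type was taken at embryonic day 9.5 (E9.5) and E10.5, from the yolk sac and from an embryo region that held the aorta-gonad-mesonephros with parts of the somites and the umbilical and vitelline vessels. These 8 groups held 2 libraries each, 16 in all. The values are FPKM as the authors deposited them, per library and gene symbol. They summed to between 586501 and 785252 per library, between 11639 and 12527 genes reached an FPKM of 1, and between 45.6% and 54.3% of the 33531 listed genes stood at 0. The number of reads per library is unknown, because FPKM carries no total. Steps between low values gave a relative depth for 11 libraries, between 0.71 and 1.1 times the reads of E9.5 embryo EC replicate 1, and no clear step for the other 4. A 2-fold error of these ratios is not excluded. Log2 values of libraries of the same group correlated across genes with r between 0.939 and 0.984, and those of different groups with r between 0.807 and 0.977. The first principal component held 47.8% of the variance and the second 13%. E10.5 yolk sac HE replicate 2 stood apart from all other libraries, at 76.1 on the first (next highest 60.1) and 56.7 on the second (next highest 27.3), with the lowest share of FPKM in ribosomal protein genes (14%) and the most named tested genes at 0 (3.02%).

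Fold changes are differences of log2(FPKM + 1) ± SE from limma with adjusted p over 13955 genes, and each group mean rests on n = 2 libraries. In the embryo, Runx1, the transcription factor that the reporter marks and that blood formation from endothelium requires, separated the sorted cell types in every library. At E9.5 its FPKM was 21.5 and 16.0 in the embryo HE libraries against 1.15 and 0.883 in the EC libraries. At E10.5 the values were 3.74 and 3.13 against 0.805 and 0.956. In the E9.5 yolk sac they were 5.81 and 8.10 against 2.37 and 2.09. In the E10.5 yolk sac Runx1 was 2.19 and 2.17 in the libraries labelled HE against 2.60 and 2.04 in EC, so this gene did not separate them. Pecam1, which encodes the CD31 used in the sort, was 47.6 and 12.6 FPKM in the libraries labelled HE of the E10.5 yolk sac, and at least 48.8 in each of the other 14. Itga2b, which encodes CD41, ranged from 31.5 to 58.5 in yolk sac EC and from 3.88 to 9.61 in embryo EC, although the gate excluded CD41 on the surface. Kit ranged from 1.66 to 16.0 over all libraries. Ptprc, which encodes CD45, did not pass the expression filter.

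**Figure D1:**
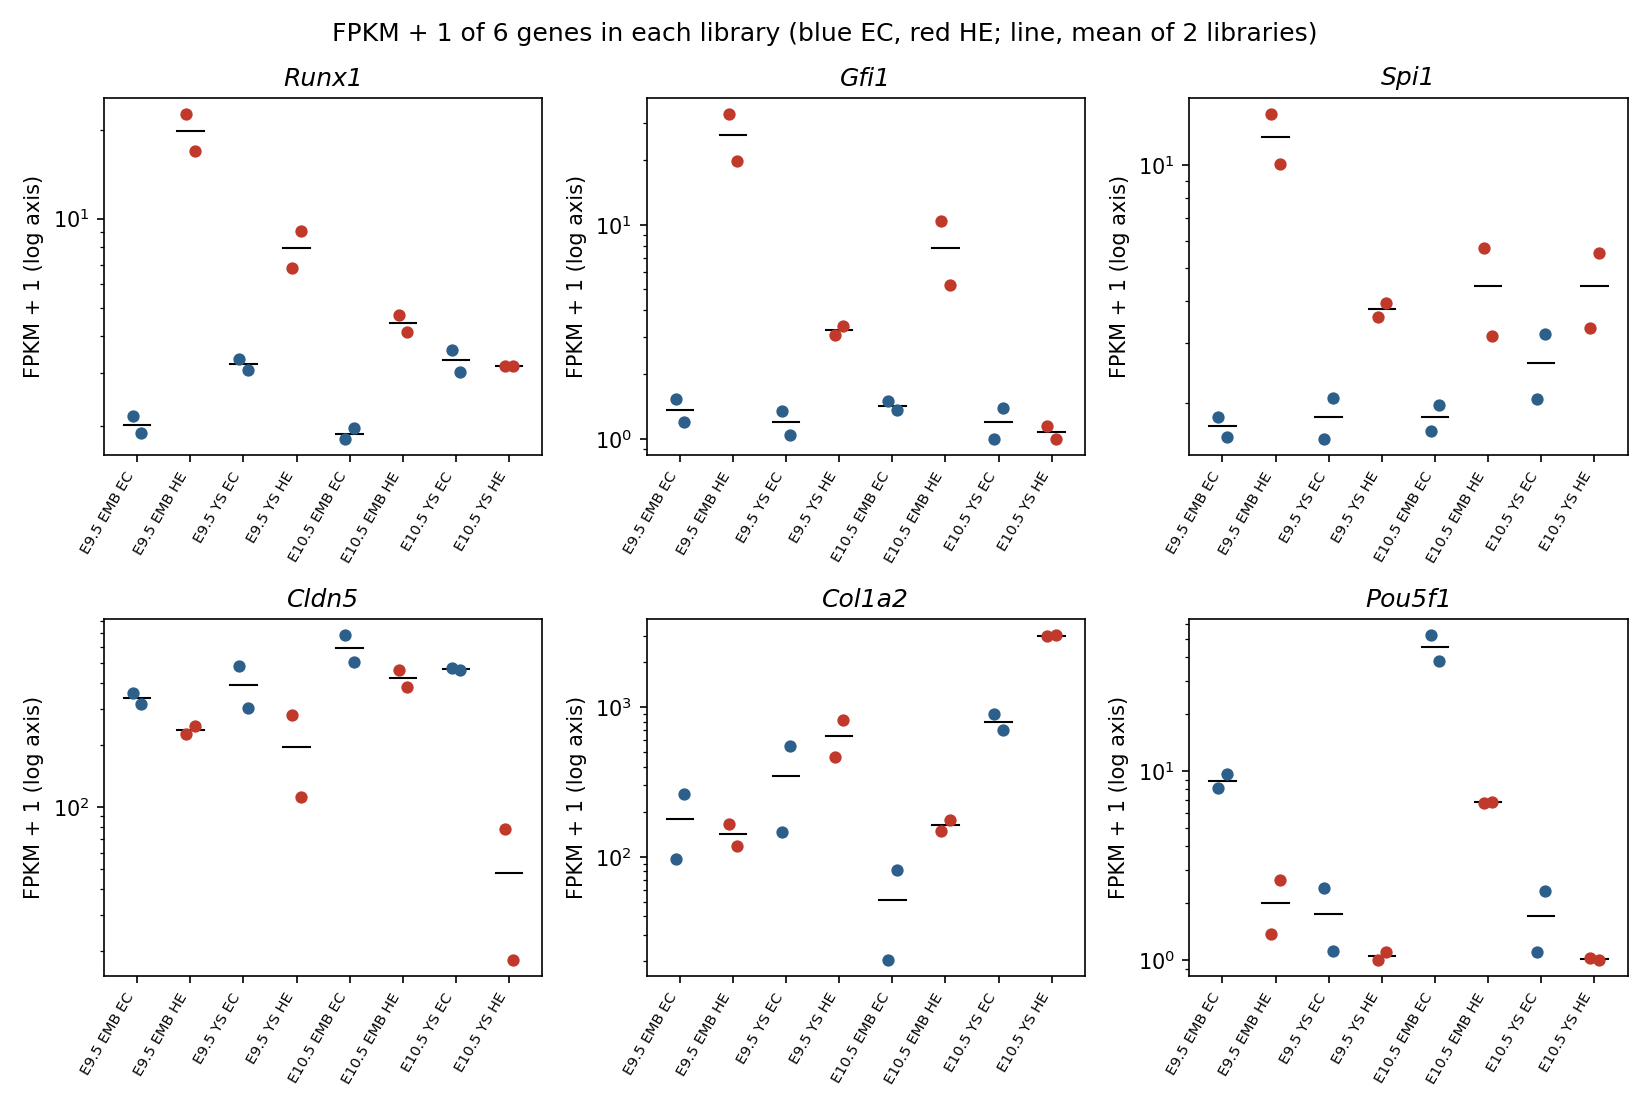
FPKM + 1 on a log axis for 6 genes in each of the 16 libraries, with EC in blue, HE in red, 1 point per library and a line at the mean of both. Runx1 stood at 21.5 and 16.0 FPKM in E9.5 embryo HE and at 2.19 and 2.17 in the libraries labelled HE of the E10.5 yolk sac, where Cldn5 was also lowest at a mean of 47.0.

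The first comparison asked which transcripts set hemogenic apart from other endothelium, averaged over both sites and stages (n = 8 libraries per cell type). Runx1 was higher in HE by 1.44 ± 0.11 (mean FPKM 7.83 against 1.61, adjusted p = 0.000247), and Gfi1, a zinc finger repressor that acts with Runx1 in silencing endothelial genes, by 1.98 ± 0.17 (adjusted p = 0.000395). Spi1, which encodes the myeloid transcription factor PU.1, rose by 1.46 ± 0.17 (mean FPKM 5.18 against 0.989, adjusted p = 0.00354). The adhesion receptor Gpr56 rose by 1.34 ± 0.18 and the integrin subunit Itgb3 by 1.20 ± 0.14, and the matrix genes Lama5 by 1.32 ± 0.18, Thbs1 by 1.26 ± 0.15 and Ltbp1 by 1.24 ± 0.17. Frem2, another extracellular matrix gene, rose by 1.42 ± 0.16 and the amino acid transporter gene Slc7a10 by 1.21 ± 0.22. Pou5f1, a transcription factor of pluripotent and germ cells, fell by 1.56 ± 0.21 (adjusted p = 0.00554). The endothelial junction gene Cldn5 fell by 1.44 ± 0.28 and Lyve1, a hyaluronan receptor of lymphatic and sinusoidal endothelium, by 1.51 ± 0.32. Gpr182 changed by −1.51, Gmfg by −1.5, Oit3 by −1.49, Cda by −1.41 and Fam167b by −1.39. Each of these 18 genes passed in every run that left out 1 library.

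In this comparison limma called 1726 of 13955 genes, 935 higher and 791 lower in HE, of which 43 and 101 differed at least 2-fold. When the libraries labelled HE of the E10.5 yolk sac were left out, an alternative added after the data were seen, 353 genes were called, 276 higher and 77 lower, and 310 of them were also among the 1726. Runx1 (1.93), Gfi1 (2.68), Spi1 (1.70), Gpr56 (1.77), Itgb3 (1.6), Lama5 (1.35), Frem2 (1.16), Thbs1 (1.00), Ltbp1 (1.04) and Pou5f1 (−1.85) then still passed. Cldn5 did not (−0.70, adjusted p = 0.0919), and neither did Lyve1 (0.0987), Gpr182 (0.085), Oit3 (0.109), Gmfg (0.0595), Cda (0.0639), Fam167b (0.0549) or Slc7a10 (0.0639). An adjusted p by itself does not tell a smaller fold change from a larger SE with fewer libraries. Leaving out 1 library moved the count over 1.5 times for 11 of the 16 libraries, from 495 without E10.5 embryo EC replicate 1 to 2786 without E10.5 yolk sac HE replicate 1.

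Of the 24 genes of general endothelial identity, 22 fell in HE (23 adjusted over the list alone), with a median of −0.97 and Pecam1 at −0.97 ± 0.25 (adjusted p = 0.0319). The shift of this list had an adjusted p of 1.05e-13 by camera, and adjusted p = 0.535 with an estimated correlation. Without the libraries labelled HE of the E10.5 yolk sac none of the 24 was called, and the median was −0.50. Pecam1's own call ended in 11 of the runs that left out 1 library, with an adjusted p of at most 0.0796. Of 21 transcription factors of blood formation 5 rose and 2 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0209, adjusted p = 0.535 with an estimated correlation), among them Bcl11a and Ikzf2. Of 18 general blood cell genes 5 rose and 1 fell (6 and 3 adjusted over the list alone), led by the actin regulators Coro1a and Was and by Fermt3 (camera adjusted p = 0.0381, adjusted p = 0.535 with an estimated correlation). Without those libraries 5 genes of each of these lists were called, all higher. Of 16 megakaryocyte genes 5 rose and 2 fell (5 and 3 adjusted over the list alone), and of 13 macrophage genes 3 rose (4 adjusted over the list alone). The 16 erythroid genes had a median of 0.46 with none called in this limma fit, or adjusted over the list alone (camera adjusted p = 0.0125, adjusted p = 0.541 with an estimated correlation).

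Lists of vessel types and signals also moved in HE. Of 20 arterial genes 4 fell (1 higher and 5 lower adjusted over the list alone, adjusted p = 0.535 with an estimated correlation), and 5 of 11 sinusoidal and lymphatic genes and 3 of 8 venous genes fell (2 higher and 6 lower, and 4 lower, adjusted over the list alone). Of 9 genes that respond to blood flow 4 fell, with the flow-induced factor Klf2 at −1.01 (7 adjusted over the list alone, camera adjusted p = 0.00046, adjusted p = 0.535 with an estimated correlation). Of 30 interferon and inflammatory genes 7 fell (7 adjusted over the list alone, camera adjusted p = 7.57e-06, adjusted p = 0.535 with an estimated correlation). None of the flow, interferon, arterial or sinusoidal genes was called without the libraries labelled HE of the E10.5 yolk sac, and their medians went from −0.499, −0.33, −0.33 and −0.34 to −0.265, −0.14, 0.03 and −0.18. Of 19 basement membrane and matrix genes 8 rose and 2 fell (9 and 3 adjusted over the list alone), with the microfibril gene Fbn1 at 0.97. Of 18 mesenchymal and somite genes 4 rose, including Pdgfrb (0.89) and Pdgfra (0.81), and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00684, adjusted p = 0.535 with an estimated correlation). The fall was that of Col1a1 and rests on its zeros in the E10.5 yolk sac. The calls of Pdgfrb and Pdgfra ended in 11 and 10 of the 16 runs that left out 1 library (adjusted p up to 0.0954), and none of these 18 was called without the E10.5 yolk sac libraries labelled HE, where the median was no smaller (0.57, against 0.48 with them). Of 11 genes of the let-7 and Lin28 axis 1 rose (3 adjusted over the list alone, camera adjusted p = 0.0423, adjusted p = 0.535 with an estimated correlation). Markers of visceral endoderm and epithelium rose for 3 of 22 (4 adjusted over the list alone, camera adjusted p = 0.00279, adjusted p = 0.535 with an estimated correlation). Of 16 genes induced by tissue dissociation 3 fell, with Dusp1 at −0.87 (3 adjusted over the list alone, camera adjusted p = 0.0125, adjusted p = 0.535 with an estimated correlation). Of 33 Hox genes 7 rose (7 and 1 lower adjusted over the list alone), of 27 cell cycle genes 5 rose and 3 fell (6 and 5), of 22 BMP and TGF-β genes 5 rose and 3 fell (9 and 5), of 18 imprinted growth genes 3 rose (7 and 1) and of 5 sex-linked genes 1 fell (1), none of these lists shifting by camera. Without the libraries labelled HE of the E10.5 yolk sac limma called no BMP and TGF-β, dissociation, sex-linked or venous gene, 1 Hox gene and 1 imprinted gene, both higher, 5 cell cycle genes higher and 1 lower, and 4 matrix, 5 megakaryocyte, 1 macrophage and 4 visceral endoderm genes, all higher.

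**Figure D2:**
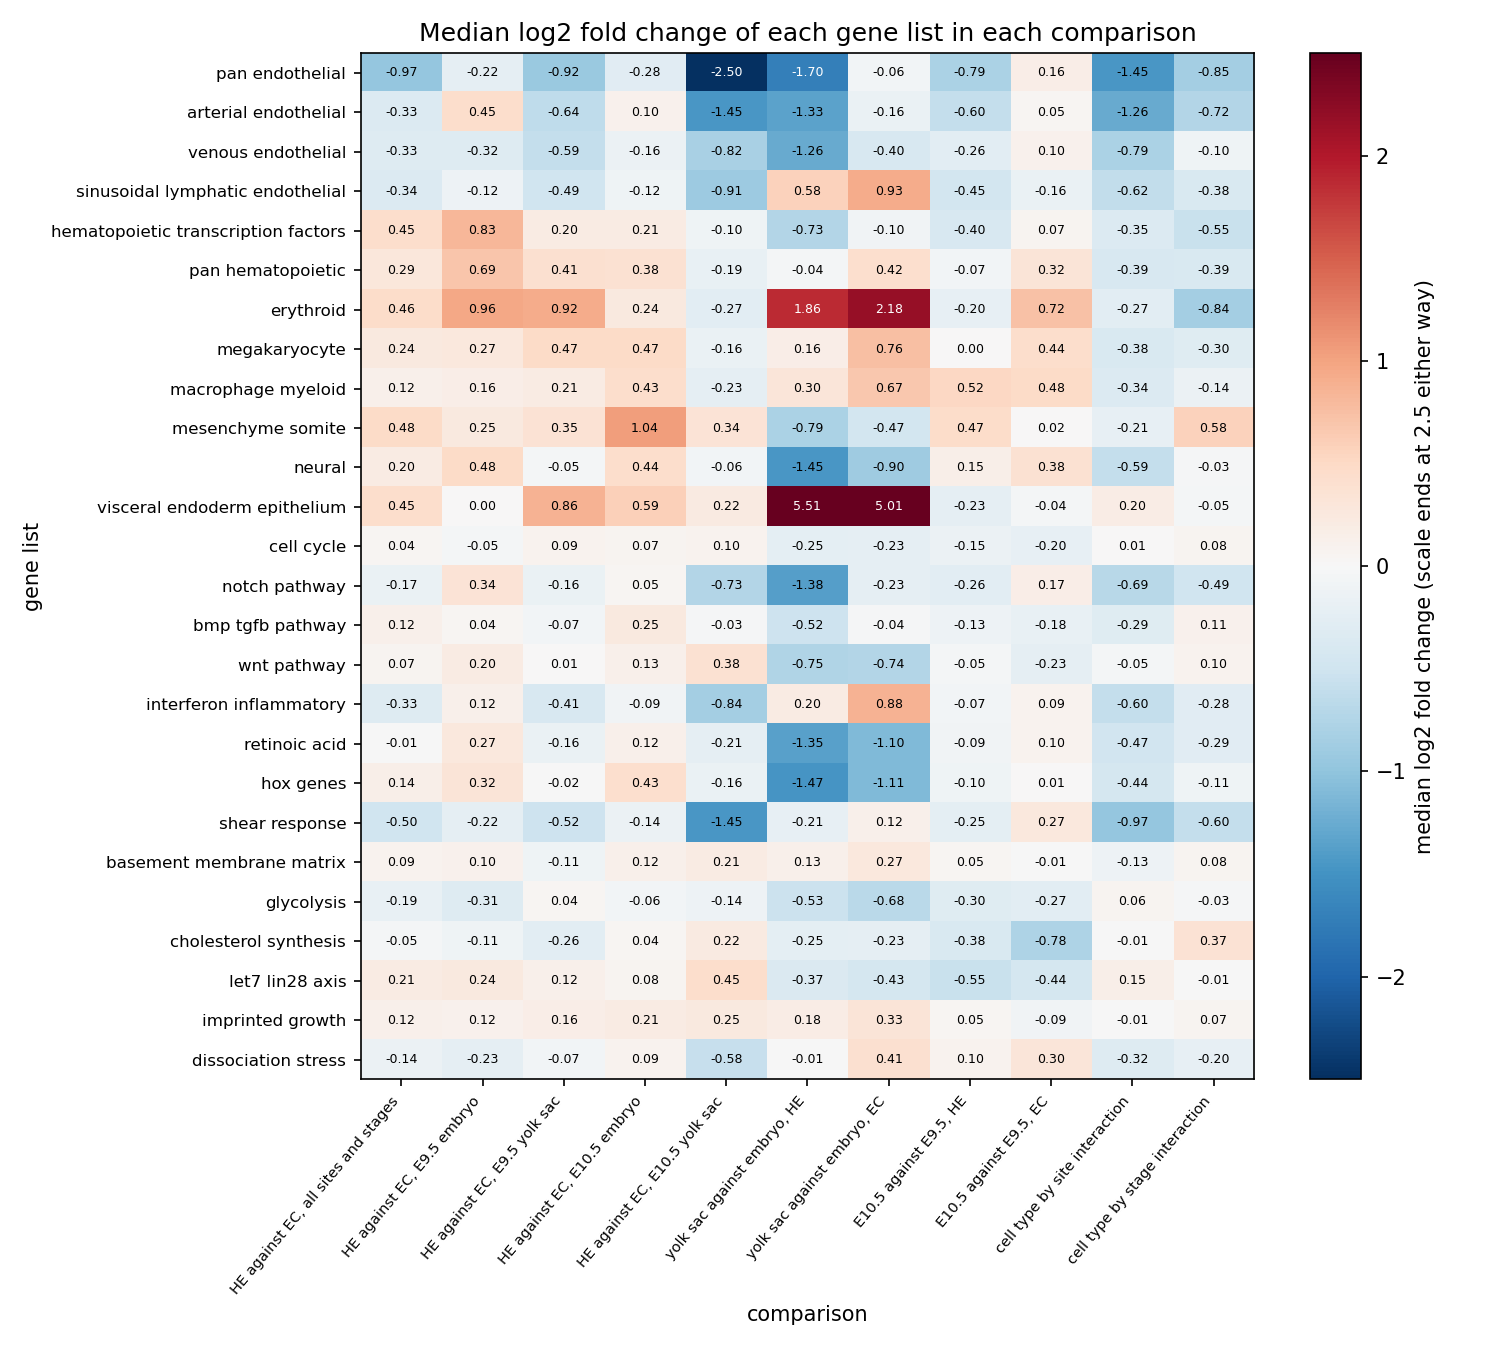
Median log2 fold change of the 27 gene lists with at least 5 tested members, except the sex-linked list (vertical), in 11 comparisons (horizontal) as a colour map whose scale ends at 2.5 in either direction. The general endothelial list reached −2.5 in the E10.5 yolk sac, and the visceral endoderm list reached 5.51 for yolk sac against embryo in HE, past the end of the scale.

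In the E9.5 embryo, where hemogenic cells line the aorta and the large vessels, HE stood apart by blood regulators. Gfi1 was 4.24 ± 0.34 higher in HE (mean FPKM 25.4 against 0.369, adjusted p = 0.000278) and Runx1 3.28 ± 0.21 (18.7 against 1.02, adjusted p = 5.66e-05). Spi1 rose by 2.81 ± 0.35 (adjusted p = 0.00656), Gpr56 by 2.74 ± 0.36, Itgb3 by 2.60 ± 0.28, Bcl11a by 1.49 ± 0.25 and Was by 1.35 ± 0.20. Of the 21 blood transcription factors 3 rose (6 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 2.16e-08, fry 0.00294, and adjusted p = 0.0575 with an estimated correlation). Of 18 general blood cell genes 2 rose (6 adjusted over the list alone, adjusted p = 0.176 with an estimated correlation). None of the 24 general endothelial genes was called (median −0.22, camera adjusted p = 0.142), and Pecam1 (−0.17), Kit (0.50) and Itga2b (0.75) did not pass. Erythroid genes had a median of 0.96 (camera adjusted p = 5.4e-05, adjusted p = 0.538 with an estimated correlation), arterial genes 0.44 (0.000319, adjusted p = 0.538 with an estimated correlation) and neural genes 0.48 (1.19e-05, adjusted p = 0.176 with an estimated correlation), with no member called by limma over all genes. Adjusted over the list alone, 3 neural genes, 1 arterial gene and no erythroid gene passed. Other lists that shifted by camera, each with adjusted p = 0.538 with an estimated correlation and no gene called, were Hox genes (median 0.32, 31 of 33 above 0, 2 higher adjusted over the list alone, camera adjusted p = 4.52e-05), Notch genes (0.345, none, 0.00921) and, downward, glycolysis genes (−0.31, none, 0.000274).

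At this stage and site limma called 22 genes, 20 higher and 2 lower, and 1225 had an unadjusted p under 0.05. Library quality weights gave 586 genes, and the 4 libraries compared gave 4 on their own. The count was 6 without E9.5 embryo EC replicate 1 or replicate 2, 5 without E9.5 embryo HE replicate 1, and 35 without either library labelled HE of the E10.5 yolk sac. Gfi1 and Runx1 passed in each of the 16 runs. Spi1 and Gpr56 did not pass without E9.5 embryo EC replicate 1 or 2 or HE replicate 1 (adjusted p up to 0.12 and 0.155), nor Itgb3 without EC replicate 2 or HE replicate 1 (up to 0.0684). Bcl11a was lost in 14 runs (up to 0.568) and Was in 4 (up to 0.292).

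In the E9.5 yolk sac, 2 genes were called among 13955, both higher in HE. Cryaa, which encodes the lens chaperone αA-crystallin, was 7.60 and 15.3 FPKM in HE against 0.035 and 0.11 in EC (3.47 ± 0.33, adjusted p = 0.00378). The other, the gene model Gm17114 at 1.66, was named after its value was seen. Runx1 was 1.29 ± 0.21 higher without passing the test (adjusted p = 0.13), and Pecam1 was −0.93 (adjusted p = 0.553). The general endothelial list had a median of −0.92 with no member called by limma over all genes or adjusted over the list alone (camera adjusted p = 4.27e-09, adjusted p = 0.547 with an estimated correlation). Markers of visceral endoderm had a median of 0.86 (camera adjusted p = 5.91e-07, adjusted p = 0.547 with an estimated correlation) and erythroid genes 0.92 (6.26e-05, adjusted p = 0.565 with an estimated correlation), again with none called. Arterial (median −0.635, camera adjusted p = 0.000191), interferon (−0.41, 1.54e-07), flow-response (−0.52, 0.00175, 1 lower adjusted over the list alone) and cholesterol synthesis genes (−0.26, 0.000219) shifted down and general blood cell genes up (0.41, 0.0334, 4 higher and 1 lower adjusted over the list alone). In each no gene was called over all genes and the adjusted p was 0.547 or 0.565 with an estimated correlation. At an unadjusted p under 0.05 there were 1336 genes. Cryaa was not called without E9.5 yolk sac EC replicate 1 (adjusted p = 0.0614), where limma called 0 genes and 652 had an unadjusted p under 0.05. The count was 3 without E10.5 embryo EC replicate 1, and 1 without either E9.5 embryo EC or either E10.5 embryo HE library. Other settings gave between 0 (pseudocount of 0.1, 1149 at an unadjusted p under 0.05) and 11 (no filter).

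In the E10.5 embryo, Gfi1 was 2.37 ± 0.34 higher in HE (adjusted p = 0.0164), Ppbp, a chemokine gene of platelets, 1.95 ± 0.26, Dok2, an adaptor of blood cells, 1.5 ± 0.24 and the actin-severing gene Gsn 1.44 ± 0.25. Runx1 was 1.24 ± 0.21 higher (mean FPKM 3.44 against 0.880, adjusted p = 0.0464). The 4 falls that the rule named were in genes known from pluripotent and germ cells, for which no list was set beforehand. Dppa5a was −2.79 ± 0.42 (13 and 8.08 FPKM in HE against 96.4 and 61.1 in EC, adjusted p = 0.0232), Pou5f1 −2.71 ± 0.42, Dppa3 −2.56 ± 0.33 and Rhox9 −2.33 ± 0.31. Nanog (−1.61), Rhox6 (−1.94), Utf1 (−2.20), Tcl1 (−1.49), Sox15 (−1.41), Dnd1 (−1.41) and Dppa4 (−1.35), named after their values were seen, fell too. Of 18 mesenchymal and somite genes none was called over all genes, 12 were higher adjusted over the list alone, and the median was 1.04 (camera adjusted p = 2.73e-09, adjusted p = 0.315 with an estimated correlation). Macrophage genes had a median of 0.43 (2 higher adjusted over the list alone, camera adjusted p = 0.000562, adjusted p = 0.185 with an estimated correlation) and the general endothelial genes −0.28 (none adjusted over the list alone, 0.00905, adjusted p = 0.842 with an estimated correlation). Many other lists shifted the same way as the macrophage genes by camera. They were Hox (median 0.43, camera adjusted p = 4.43e-05, 0.323 with an estimated correlation), megakaryocyte (0.47, 1 called, 0.000562 and 0.315), visceral endoderm (0.59, 0.00123 and 0.559), general blood cell (0.38, 0.00266 and 0.315) and neural genes (0.44, 0.00272 and 0.323), and less far BMP and TGF-β (0.25, 0.00966 and 0.315), basement membrane (0.12, 0.0273 and 0.559) and blood transcription factor genes (0.21, 1 called, 0.0341 and 0.381). Adjusted over the list alone 0, 4, 0, 5, 3, 1, 4 and 4 genes of these lists were higher by limma.

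Here limma called 29 genes, 12 higher and 17 lower, with 1029 at an unadjusted p under 0.05, and quantile normalization gave 6 higher and 21 lower. Other settings gave between 5 (pseudocount of 0.1) and 94 genes (no filter). The count was 9 without E10.5 embryo EC replicate 1, 33 without its replicate 2, 14 and 15 without E10.5 embryo HE replicate 1 and 2, and 17 without either E9.5 embryo EC or either E9.5 yolk sac HE library. The Runx1 call was lost in all 16 runs (adjusted p up to 0.367). Gfi1 was lost without E10.5 embryo EC replicate 1 or 2 or HE replicate 1 (up to 0.156), and Ppbp, Dppa5a and Rhox9 without EC replicate 1 or either HE library (up to 0.156, 0.296 and 0.156). Dppa3 was lost without EC replicate 1 or HE replicate 2 (up to 0.134), Pou5f1 in 8 runs (up to 0.313), and Dok2 and Gsn in 10 (up to 0.281 and 0.371).

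In the E10.5 yolk sac, the libraries labelled HE, of which replicate 2 stood apart from all others, were low in endothelial transcripts. Of the 24 general endothelial genes 23 fell (24 adjusted over the list alone), with a median of −2.5 (camera adjusted p = 5.83e-19, fry 0.0178, and adjusted p = 0.42 with an estimated correlation). Within the libraries numbered 1 the median difference was −1.89 and within those numbered 2 it was −3.30, with 24 of 24 lower in both. Cldn5 fell by 3.65 ± 0.56 (mean FPKM 47.0 against 469, adjusted p = 0.00893), the adhesion gene Icam2 by 3.76 ± 0.73, Gja4, a gap junction gene of arteries, by 3.52 ± 0.62, and Pecam1 by 2.56 ± 0.50. Of 20 arterial genes 13 fell (13 adjusted over the list alone, adjusted p = 0.42 with an estimated correlation), with Sox17 at −3.39 and the Notch ligand Dll4 at −2.64. Of 19 Notch pathway genes 8 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 0.543 with an estimated correlation), with the Notch targets and modifiers Nrarp at −1.98 and Mfng at −2.76. Stab1 (−3.20) and Lyve1 (−3.01) were among 5 of 11 sinusoidal genes that fell (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.42 with an estimated correlation). Klf2 (−2.62) and Nos3 (−2.80) were among 5 of 9 flow-response genes that fell (7 adjusted over the list alone, adjusted p = 0.42 with an estimated correlation).

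In the same comparison of the E10.5 yolk sac, blood transcription factors divided, with Lyl1 at −1.66, Hhex at −2.46 and Gata2 at −1.46 lower and Hlf at 1.46 higher among 21 (3 and 1 adjusted over the list alone, camera adjusted p = 0.671). Runx1 was −0.06 ± 0.21 (adjusted p = 0.898), Kit −0.62 (adjusted p = 0.285) and Itga2b −2.0 ± 0.31 (adjusted p = 0.00893). Of 30 interferon genes 7 fell (17 adjusted over the list alone, adjusted p = 0.42 with an estimated correlation). Among the largest rises were Ece1 (3.35 ± 0.81), the RNA-binding protein gene Celf2 (3.11 ± 0.42) and the cell cycle factor E2f3 (3.00 ± 0.50). Ece1 was 548 and 5527 FPKM in the libraries labelled HE against 103 and 277 in EC. Of 19 basement membrane and matrix genes 5 rose, among them Fbn1 (1.52), Fn1 (1.31) and Lamc1 (0.88), and 3 fell, among them Mmrn2 at −2.64 (8 and 4 adjusted over the list alone). Of 16 genes induced by tissue dissociation 3 fell, with Dusp1 at −2.26 (5 adjusted over the list alone, camera adjusted p = 0.000177, adjusted p = 0.42 with an estimated correlation). Of 11 genes of the let-7 and Lin28 axis 1 rose (1 adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.616 with an estimated correlation). Of 18 mesenchymal and somite genes none rose and 2 fell, Tcf15 at −1.68 and Col1a1 by its zeros (0 and 2 adjusted over the list alone, median 0.34, camera adjusted p = 0.279). Collagen genes stood high without passing, with Col1a2 at 2982 and 3015 FPKM against 901 and 701 (1.91, adjusted p = 0.102). Col1a1 was listed at 0 in both libraries labelled HE and at 1817 and 1190 in EC. Limma called 1335 genes, 431 higher and 904 lower. The count was 13 without E10.5 yolk sac EC replicate 1, 470 without its replicate 2, 2649 without HE replicate 1 and 19 without HE replicate 2, and 1 with library quality weights or with these 4 libraries alone. Of 73 named genes called, 3 passed in every run that left out 1 library. They were Lyl1, Dusp1 and, by its zeros, Col1a1. The others named here were lost without EC replicate 1 or HE replicate 2 (Cldn5 up to 0.0588, Icam2 up to 0.0663, Gja4 up to 0.0628, Pecam1 up to 0.0921, Ece1 up to 0.15), and Icam2, Pecam1, Lyve1, Hhex, Gata2, Fn1 and Lamc1 also without EC replicate 2. Hlf was lost in 15 runs (up to 0.167).

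**Figure D3:**
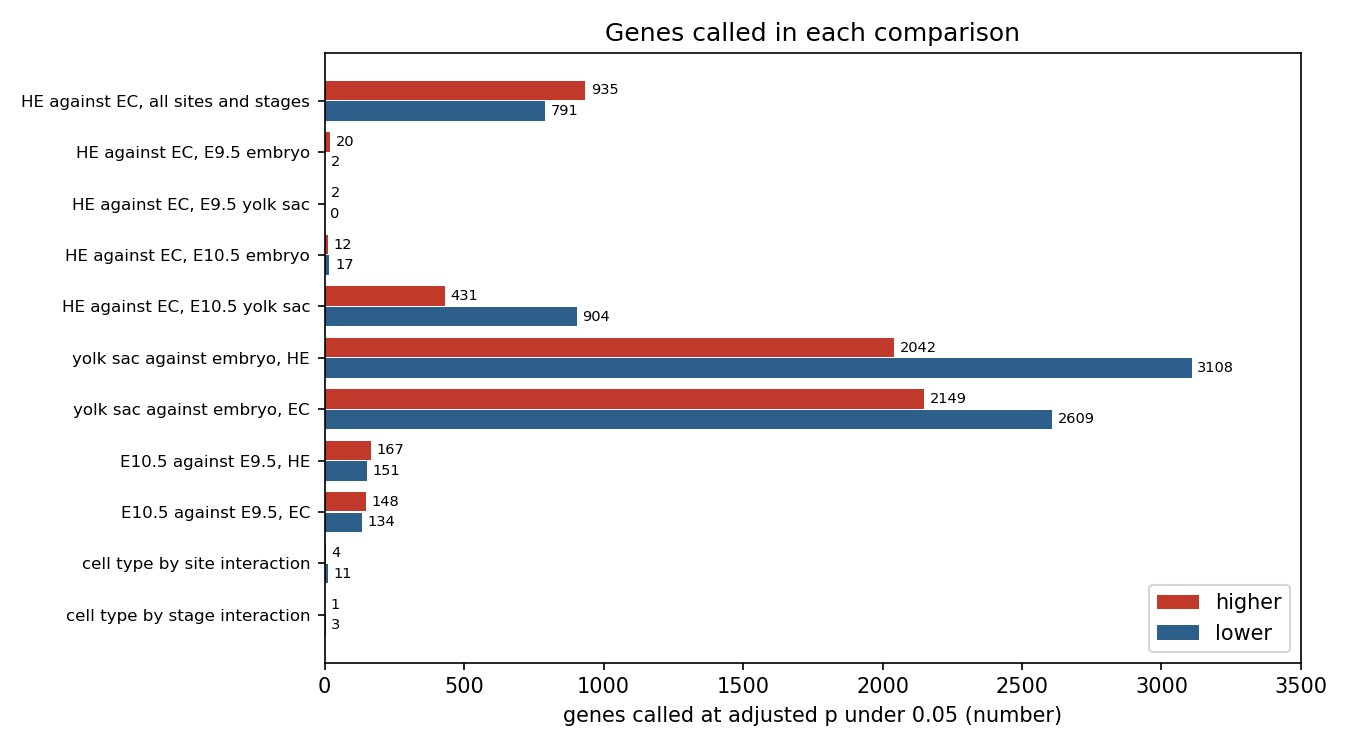
Number of genes higher and lower at an adjusted p under 0.05 (horizontal bars from 0) in each of the 11 comparisons by limma. Yolk sac against embryo gave 5150 calls in HE and 4758 in EC, and HE against EC gave 22 in the E9.5 embryo and 1335 in the E10.5 yolk sac.

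The comparison of sites asked how libraries of the yolk sac differed from those of the embryo within a sorted cell type. In HE, the yolk sac libraries were higher in transcripts of visceral endoderm, the epithelium that covers the yolk sac. The visceral endoderm, erythroid, megakaryocyte, macrophage, neural, and mesenchyme and somite lists hold markers of cells other than endothelium that the gates or dissection could include. In the comparisons of site and of stage, such cells cannot be told apart from a difference of the endothelium itself. The apolipoprotein gene Apoa1 rose by 8.26 ± 0.60 (mean FPKM 1442 against 6.37, adjusted p = 1.36e-06), Afp, which encodes α-fetoprotein, by 7.81 ± 0.63 (2119 against 9.86), S100g by 8.16 ± 0.48, Ttr by 7.67 ± 0.53 and Apoa2 by 6.92 ± 0.30. Spink3, Apoc2 and Rbp4 rose by 7.45, 7.43 and 7.29. Crabp1, a retinoic acid binding protein gene, fell by 5.36 ± 0.26 (4.28 against 164, adjusted p = 9.02e-08), the Wnt receptor Fzd10 by 4.41 ± 0.13, and Tcf15 and Meox1, genes of the paraxial mesoderm, by 3.92 ± 0.26 and 3.69 ± 0.25. Crabp2, Tbx1, Lef1 and Ly6h fell by 3.96, 3.90, 3.78 and 3.55. All these genes passed without the E10.5 yolk sac libraries labelled HE, when the comparison rests on E9.5 alone (Apoa1 7.50, Afp 6.77, Crabp1 −4.10), and in every run that left out 1 library.

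Of 22 visceral endoderm genes 16 rose in yolk sac HE (18 adjusted over the list alone), with a median of 5.51 (camera adjusted p = 5.48e-18, adjusted p = 0.0999 with an estimated correlation), and 15 rose without the libraries labelled HE of the E10.5 yolk sac. All 16 erythroid genes rose (16 adjusted over the list alone, median 1.86, camera adjusted p = 9.45e-08, adjusted p = 0.336 with an estimated correlation), and 8 without those libraries, at a median no smaller (2.04). Of 33 Hox genes 30 fell and 1 rose (30 and 1 adjusted over the list alone, camera adjusted p = 3.62e-13, adjusted p = 0.0999 with an estimated correlation), and all 10 neural genes fell (10 adjusted over the list alone, adjusted p = 0.0999 with an estimated correlation). Without those libraries 25 Hox and 8 neural genes fell. Of 20 arterial genes 16 fell (17 adjusted over the list alone, adjusted p = 0.324 with an estimated correlation), with the Notch target Hey1 at −3.41 and the ligand Jag2 at −3.09, and 11 fell without those libraries. The sinusoidal genes Lyve1 (4.25), Stab2 (3.63) and Maf (3.20) were among 5 of 11 that rose (5 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation), and 5 rose without those libraries. General endothelial genes fell for 22 of 24 (22 adjusted over the list alone, median −1.70, adjusted p = 0.471 with an estimated correlation), and for 5 without those libraries. The medians without them were −0.63 for general endothelial, −1.30 for arterial, −1.55 for Hox, −1.32 for neural and 5.11 for visceral endoderm genes. Of 21 blood transcription factors 5 rose and 12 fell (5 and 12 adjusted over the list alone), with Gfi1 at −2.89 and Runx1 itself at −0.90 ± 0.15 (adjusted p = 0.000745).

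Signalling and metabolic lists also differed by site in HE. Of 19 Wnt genes 10 fell and 2 rose, of 13 retinoic acid genes 9 fell and 1 rose and of 19 Notch genes 13 fell (10 and 2, 9 and 1, and 14 adjusted over the list alone, with adjusted p = 0.324, 0.0999 and 0.324 with an estimated correlation). Of 19 glycolysis genes 10 fell (11 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation) and of 27 cell cycle genes 9 (9 adjusted over the list alone, adjusted p = 0.324 with an estimated correlation). Hmga2 (−2.88) and Mycn (−1.83) were among 4 of 11 genes of the let-7 and Lin28 axis that fell (4 adjusted over the list alone, adjusted p = 0.481 with an estimated correlation). Without the libraries labelled HE of the E10.5 yolk sac 10 Wnt, 8 retinoic acid, 7 Notch and 9 glycolysis genes fell, but only 1 cell cycle gene, and 3 genes of the let-7 and Lin28 axis. Of 30 interferon genes 10 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0196, adjusted p = 0.513 with an estimated correlation), and of 13 macrophage genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.00688, adjusted p = 0.147 with an estimated correlation), against 7 and 1 that rose without those libraries. Of 18 mesenchymal and somite genes 5 rose and 10 fell (6 and 10 adjusted over the list alone), and 8 fell and none rose without those libraries. Limma called 5150 genes, 2042 higher and 3108 lower, of which 955 and 952 differed at least 2-fold. With median-of-ratios scaling the split was 2480 higher and 2233 lower, and the median over all genes moved from −0.14 to −0.03. Without those libraries the count was 2122, of which 1982 were also among the 5150, from fewer libraries.

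In EC, the site comparison gave 4758 genes, 2149 higher and 2609 lower in the yolk sac. Apoa1 rose by 8.11 ± 0.60, Afp by 8.06 ± 0.63, Ttr by 7.29 ± 0.53 and S100g by 7.11 ± 0.48, and Fzd10 fell by 4.69 ± 0.13, Tbx1 by 3.99 ± 0.14, Dppa5a by 3.82 ± 0.30 and Crabp1 by 3.75 ± 0.26. Of 22 visceral endoderm genes 20 rose (20 adjusted over the list alone, median 5.01, adjusted p = 0.13 with an estimated correlation), as did all 16 erythroid genes (16 adjusted over the list alone, median 2.18, adjusted p = 0.272 with an estimated correlation). Of 21 blood transcription factors 5 rose and 5 fell, Lmo2 at −1.99 among the falls (5 and 5 adjusted over the list alone, camera adjusted p = 0.989), and of 18 general blood cell genes 8 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0022, adjusted p = 0.205 with an estimated correlation). Of 30 interferon genes 20 rose and 1 fell (21 and 3 adjusted over the list alone, camera adjusted p = 1.18e-07, adjusted p = 0.21 with an estimated correlation), with Bst2 at 2.66 and Isg15 at 2.57, and of 13 macrophage genes 9 rose (9 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation). Of 16 megakaryocyte genes 9 rose and 4 fell (10 and 4 adjusted over the list alone, adjusted p = 0.272 with an estimated correlation), with the platelet chemokine gene Pf4 at 2.76. The sinusoidal genes Lyve1 (5.48), Mrc1 (5.04) and Stab2 (4.74) were among 7 of 11 that rose, with 1 that fell (7 and 1 adjusted over the list alone, adjusted p = 0.135 with an estimated correlation). Of 24 general endothelial genes 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.691). Of 33 Hox genes 25 fell and 1 rose (25 and 1 adjusted over the list alone, adjusted p = 0.135 with an estimated correlation), and of 10 neural genes 9 fell (10 adjusted over the list alone, adjusted p = 0.135 with an estimated correlation). Falls in Wnt (11, with 3 rises), retinoic acid (7, with 2 rises), glycolysis (11), cell cycle (8) and let-7 and Lin28 genes (6) also went with shifts by camera (adjusted p = 0.00295, 0.00621, 0.000361, 0.00332 and 0.0013), which did not hold with an estimated correlation (0.272, 0.191, 0.343, 0.135 and 0.272). Runx1 was 0.75 ± 0.15 higher (adjusted p = 0.0026) and Itga2b 2.57 (adjusted p = 5.55e-06), Kit fell by 1.09, and Pecam1 was −0.33 (adjusted p = 0.509). Each of these named genes passed in every run that left out 1 library, except Pecam1, which was never called.

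Both site comparisons use separate libraries, but 1 fit gave them a shared estimate of each gene's spread. A gene with a small spread is favoured in both, so the counts for independent lists, here and below, are only a rough baseline. The site comparisons shared 1482 genes called higher, against 314 for independent lists of these sizes, and 1790 called lower, against 581. Their fold changes correlated across genes with r = 0.837, genes not being independent replicates.

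The comparison of stages asked what changed from E9.5 to E10.5. In HE, Runx1 fell by 1.73 ± 0.15 (mean FPKM 2.81 against 12.8, adjusted p = 0.000368) and Gfi1 by 1.69 ± 0.24 (adjusted p = 0.00707). The retinoic acid degrading enzyme gene Cyp26a1 fell by 1.89 ± 0.26, the carbonic anhydrase gene Car4 by 1.79 ± 0.26, the monoamine transporter gene Slc18a2 by 1.71 ± 0.20, Emb by 1.67 ± 0.24 and Gap43 by 1.65 ± 0.30. The collagen genes Col2a1 (2.63 ± 0.22, adjusted p = 0.000298), Col9a2 (1.93 ± 0.39) and Col12a1 (1.89 ± 0.24) rose, as did Actg2 (2.56 ± 0.40), Cpz (2.15), Gabrp (2.02), Wfdc1 (1.94) and Ppbp (1.89 ± 0.19). Of 18 mesenchymal and somite genes none rose and 1 fell, Col1a1 by its zeros (0 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 0.00791, adjusted p = 0.621 with an estimated correlation). Of 13 macrophage genes 3 rose (8 adjusted over the list alone), the complement genes C1qc (1.25) and C1qb (1.40) and the receptor Csf1r (0.72), and this list held with an estimated correlation (camera adjusted p = 6.18e-07, and adjusted p = 0.0254 with an estimated correlation). These 3 genes were low, with means of 0.11 to 0.97 FPKM at E9.5 and 1.72 to 2.70 at E10.5. Such low genes can pass the filter through their E10.5 values alone, which favours a rise. Hmga2 (−1.21) and Lin28a (−1.34) were among 4 of 11 genes of the let-7 and Lin28 axis that fell (7 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation). None of 17 cholesterol synthesis genes was called over all genes and 10 were lower adjusted over the list alone (camera adjusted p = 5.21e-06, adjusted p = 0.437 with an estimated correlation). Of 21 blood transcription factors 1 rose and 3 fell (1 and 6 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation), with Cebpa at 1.31. Of 20 arterial genes 2 fell (11 adjusted over the list alone, median −0.60, camera adjusted p = 6.37e-05, adjusted p = 0.621 with an estimated correlation). Glycolysis (median −0.30, 9e-04 and 0.621), cell cycle (−0.15, 0.0143 and 0.437) and neural genes (0.15, 0.0111 and 0.527) shifted too, with 1 gene called in each. Of 24 general endothelial genes none was called, in either adjustment, at a median of −0.79 (camera adjusted p = 2.24e-05, adjusted p = 0.664 with an estimated correlation), and the median was 0.18 without the libraries labelled HE of the E10.5 yolk sac.

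Across stages in HE limma called 318 genes, 167 higher and 151 lower. Median-of-ratios scaling gave 231 and 90, and quantile normalization 250 and 109. Without the libraries labelled HE of the E10.5 yolk sac, when the comparison rests on the embryo alone, the count was 303, of which 133 were also among the 318. Runx1 (−2.14), Gfi1 (−1.80), Cyp26a1 (−2.61), Car4 (−2.94), Slc18a2 (−1.86), Emb (−1.54), Actg2 (2.77), Gabrp (1.86) and Ppbp (1.58) then passed, and Col2a1 (1.28, adjusted p = 0.0503), Cpz (0.20), Wfdc1 (1.31), Col9a2 (0.35), Col12a1 (0.68) and Gap43 (−0.42) did not. Leaving out 1 library moved the count over 1.5 times for 9 libraries, from 95 without E9.5 embryo HE replicate 1 to 853 without E10.5 yolk sac HE replicate 1. The calls of Cpz, Wfdc1, Col9a2, Gap43, C1qb and Csf1r ended in 9, 5, 7, 4, 8 and 7 of the 16 runs (adjusted p up to 0.151).

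In EC, 11 lists moved with stage by camera, among them cholesterol synthesis and macrophage genes. Of 17 cholesterol synthesis genes 9 fell (16 adjusted over the list alone), with Cyp51 at −0.78, Sc5d at −0.83, Insig1 at −0.82 and Sqle at −0.79 (camera adjusted p = 1.61e-14, fry 0.00132, and adjusted p = 0.122 with an estimated correlation). Of 13 macrophage genes 4 rose (8 adjusted over the list alone), C1qb (1.95), C1qa (1.20), C1qc (1.07) and the signalling adaptor Tyrobp (0.93), and this list held with an estimated correlation (camera adjusted p = 1.04e-08, and adjusted p = 0.0137 with an estimated correlation). These 4 genes too were low, with means of 0.04 to 0.50 FPKM at E9.5 and 1.47 to 4.5 at E10.5, so the filter favours their rise in the same way. Lin28a (−1.55) and Hmga2 (−0.94) fell, 2 of the 11 genes of their list (9 adjusted over the list alone, adjusted p = 0.166 with an estimated correlation). Of 16 megakaryocyte genes 2 rose, Pf4 (1.80) and Ppbp (1.16) (6 adjusted over the list alone, adjusted p = 0.166 with an estimated correlation). Markers of other cells and genes of tissue handling shifted upward by camera, though not with an estimated correlation. They were 16 erythroid genes (none called in either adjustment, median 0.73, camera adjusted p = 0.000142, adjusted p = 0.523 with an estimated correlation), 10 neural genes (5 adjusted over the list alone, median 0.38, 0.000208 and 0.166), 18 general blood cell genes (2 called, 4 higher and 2 lower adjusted over the list alone, median 0.32, 0.000678 and 0.166) and 16 dissociation genes (1 adjusted over the list alone, median 0.30, 0.000245 and 0.371). Interferon genes shifted against other genes with none called in either adjustment (median 0.09, 21 of 30 above 0, 0.00587 and 0.523, fry 0.538), and cell cycle (median −0.20, 1 called, 0.000533 and 0.122) and glycolysis genes fell (median −0.27, none called and 9 adjusted over the list alone, 0.00221 and 0.523). Among single genes the adult globin gene Hbb-bt rose by 2.67 ± 0.40 (adjusted p = 0.00973), Actg2 by 2.40 ± 0.40, the fatty acid binding protein gene Fabp4 by 2.37 ± 0.48 and the muscle myosin gene Mylpf by 2.09 ± 0.33. Wnt6 fell by 1.93 ± 0.37. Rpl35a-ps2 (−4.31) and Rpl9-ps6 (−2.15) fell as well, but they are near-identical copies of other genes, so their values are uncertain, and 47 ribosomal pseudogenes were low in E10.5 yolk sac EC replicate 1 (mean log2 value 1.51) and in HE replicate 1 (1.81) against 2.88 to 3.82 in the other 14 libraries. Runx1 was −0.03 (adjusted p = 0.938).

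Across stages in EC limma called 282 genes, 148 higher and 134 lower. Median-of-ratios scaling gave 189 and 86, and quantile normalization 200 and 83. The count moved over 1.5 times for 9 libraries, from 39 without E9.5 embryo EC replicate 1 to 547 without E10.5 yolk sac HE replicate 2. Cyp51, Sc5d, Insig1 and Lin28a passed in every run. Hbb-bt and Mylpf were lost without E9.5 or E10.5 embryo EC replicate 1 (adjusted p up to 0.0552 and 0.0562), C1qb likewise (up to 0.0534), Sqle without E10.5 embryo EC replicate 1 (0.051), and Actg2 also without E10.5 yolk sac EC replicate 1 (up to 0.0745). Fabp4, Wnt6, C1qc, C1qa, Tyrobp, Pf4 and Hmga2 were lost in 8, 7, 8, 14, 14, 12 and 5 runs (up to 0.183). The stage comparisons of HE and EC shared 65 genes called higher, against 1.77 for independent lists, and 27 called lower, against 1.45 (r = 0.419 across genes).

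The interaction of cell type with site tested whether the HE to EC difference was smaller or larger in the yolk sac. It was smaller for Runx1 (−1.65 ± 0.21, adjusted p = 0.0149) and Gfi1 (−2.65 ± 0.34, adjusted p = 0.0149), which were 3.28 and 4.24 higher in HE of the E9.5 embryo and 1.29 and 1.44 in the E9.5 yolk sac. The hyaluronan receptor gene Cd44 also differed (−1.61 ± 0.21). Limma called 15 genes, 4 higher and 11 lower (8 and 11 with quantile normalization), with 1725 at an unadjusted p under 0.05. The general endothelial list lay lower (median −1.45, 21 adjusted over the list alone, camera adjusted p = 3.56e-15, adjusted p = 0.169 with an estimated correlation), as did the arterial list (median −1.26, 17 adjusted over the list alone, adjusted p = 0.163 with an estimated correlation). Another 12 lists of blood, neural, signalling, Hox, flow and dissociation genes lay lower by camera, with medians from −0.295 (BMP and TGF-β) to −0.97 (flow response) and an adjusted p between 0.163 and 0.5 with an estimated correlation. Without the libraries labelled HE of the E10.5 yolk sac limma called 0 genes and 696 had an unadjusted p under 0.05, in a test on E9.5 alone. Runx1 was then −1.99 ± 0.30 (adjusted p = 0.177) and Gfi1 −2.80 ± 0.49 (adjusted p = 0.179), no smaller but with a larger SE, while the medians of the endothelial and arterial lists were −0.67 and −0.997. The count ranged from 0 without E9.5 embryo EC replicate 1 (1395 at an unadjusted p under 0.05) to 395 without E10.5 yolk sac HE replicate 1. Runx1 was lost in 7 runs (adjusted p up to 0.0633), Cd44 in 6 (up to 0.0645), and Gfi1 without E9.5 embryo EC or HE replicate 1 or E9.5 yolk sac EC replicate 1 (up to 0.0633).

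The interaction of cell type with stage gave 4 genes, of which Runx1 was lower at E10.5 by −1.69 ± 0.21 (adjusted p = 0.022). The other genes, named after their values were seen, were the gene models Gm22457 (2.05), Gm22767 (−1.6) and Gm25791 (−6.25). By limma 887 genes had an unadjusted p under 0.05. By camera 13 lists shifted, none with an estimated correlation (adjusted p between 0.258 and 0.614), among them general endothelial (median −0.85), erythroid (−0.84), arterial (−0.725), blood transcription factor (−0.55), mesenchymal (0.58) and cholesterol synthesis genes (0.37). These medians were −0.05, −0.70, −0.31, −0.43, 0.82 and 0.185 without the libraries labelled HE of the E10.5 yolk sac. The Runx1 call was lost in 10 of the 16 runs (adjusted p up to 0.0984) and without the libraries labelled HE of the E10.5 yolk sac (−2.04 ± 0.30, adjusted p = 0.128), and the count ranged from 0 without E9.5 embryo EC replicate 2 (603 at an unadjusted p under 0.05) to 42 without E10.5 yolk sac HE replicate 1. Called genes of HE against EC shared 3 rises between the E9.5 and the E10.5 embryo, against 0.0172 for independent lists (r = 0.3 across genes), and none between the E10.5 embryo and yolk sac in either direction, against 0.371 and 1.1 (r = 0.275). These overlaps compare calls and are not tests of a difference.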

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

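Tests chosen after the result was seen were those of mesenchymal cells and of Runx1 in the E10.5 yolk sac, of stage for the germ-cell genes, and of sequencing depth for the pseudogenes, and so were all results without the libraries labelled HE of the E10.5 yolk sac. The other tests were set before their results were seen.

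Each of 10 results was singled out because the effect of cell type differed between sites or stages by an interaction test in limma. For the interaction with site these were Runx1 (−1.65, adjusted p = 0.0149), Gfi1 (−2.65, 0.0149), Cd44 (−1.61, 0.0149), Aes (−2.10, 0.0204) and Hist3h2ba (−1.85, 0.0204), where HE stood lower against EC in the yolk sac than in the embryo, and Rhox9 (2.00, 0.0315), Rhox6 (1.58, 0.0204) and Rbmxl2 (1.47, 0.0149). For the interaction with stage it was Runx1 (−1.69, 0.022). Runx1 was 3.28 and 1.24 higher in HE of the E9.5 and E10.5 embryo, and 1.29 and −0.06 in the E9.5 and E10.5 yolk sac. Gfi1 in the same order was 4.24, 2.37, 1.44 and −0.14, and Cd44 1.10, 0.96, −0.30 and −0.87. Aes was 0.94, 0.51, −0.72 and −2.01, and Hist3h2ba 0.39, 1.14, −0.65 and −1.53. Rhox9 was −1.60, −2.33, −0.54 and 0.62, Rhox6 −1.22, −1.94, −0.00 and −0.00, and Rbmxl2 −0.76, −2.29, −0.04 and −0.07. Col1a1 passed the same rule with a fitted value of −5.79, which rests on its being listed at 0 in both libraries labelled HE of the E10.5 yolk sac (1817 and 1190 FPKM in EC), and without them its value was 1.13. None of the 9 interactions with site was called without these libraries, where the comparison rests on E9.5 alone and the SE is larger (0.304 against 0.213 for Runx1). Runx1 (−1.99, adjusted p = 0.177) and Gfi1 (−2.80, 0.179) were then no smaller, and Cd44 (−1.40), Aes (−1.67), Rhox6 (1.21), Hist3h2ba (−1.04), Rhox9 (1.05) and Rbmxl2 (0.72) were smaller. Leaving out 1 library ended the calls of Rhox9 in 13 of 16 runs, Hist3h2ba in 11, Rhox6 in 10, Aes in 9, Runx1 with site in 7 and with stage in 10, Cd44 in 6 and Col1a1 in 5. Rbmxl2 was lost without E9.5 embryo EC or HE replicate 1 (adjusted p up to 0.0633) and Gfi1 without these or E9.5 yolk sac EC replicate 1 (up to 0.0633).

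The libraries labelled HE of the E10.5 yolk sac were lower in endothelial genes, with a median of −2.5 over 24 genes. A difference in scaling is argued against. With median-of-ratios scaling and quantile normalization, in either order, medians were −2.37 (SD 0.62 over genes) and −2.47. Runx1 was −0.0583 ± 0.213 there (lowest other setting 1.24). This cannot decide on enrichment of cells that transcribe Runx1, whose RNA other cells could dilute. Mesenchymal cells among the sorted cells remain a candidate explanation: over 14 fibrous matrix genes chosen without Col1a2 and Col3a1, the libraries stood 0.999 (SD 0.512) and 1.57 above the mean of EC. The CD31 gate was meant to remove such cells, but Pecam1, which encodes CD31, was itself lower there (mean FPKM 30.1 against 151). The gate therefore does not decide against them. The mesenchymal and somite list set beforehand decides nothing either. Its 18 genes went both ways, with a median of 0.34 and 14 above 0, and their SD of 2.74 was widened by Col1a1 at its zeros (−10.52). A rise of mesenchymal genes in HE was also not particular to the yolk sac. In the E10.5 embryo the median of that list was 1.04, while the general endothelial median was only −0.28. Levels differed between the sites, however. Col1a2 was 147 and 175 FPKM in E10.5 embryo HE against 2982 and 3015 in the yolk sac libraries labelled HE. Pdgfra lay closer, at 5.65 and 9.06 against 12.95 and 8.59. The small endothelial fall in the embryo therefore does not decide against mesenchymal cells in the yolk sac. The matrix genes alone do not single out the cause of the endothelial fall. A change within the cells as they leave the endothelium at this stage and site stays open as untested.

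Genes known from germ cells were higher in EC than in HE of the E10.5 embryo, with Pou5f1 at 51.3 and 37.3 FPKM against 5.80 and 5.87 and Dppa3 at 39.6 and 24.7 against 5.98 and 3.27. In embryo EC, 11 such genes were higher at E10.5 than at E9.5 by a median of 2.07 (SD 0.635). They had been picked for their values in these same E10.5 EC libraries, which favours a rise, and genes are not independent replicates. The rise alone therefore does not decide against expression left from earlier stages. Primordial germ cells among the sorted cells may account for it: of 4 further markers that passed the filter, 3 were higher in both EC than in both HE libraries (Tfap2c −1.08, Alpl −1.0, Sall4 −0.63, but Prdm1 −0.21), where chance gives 1 in 6 for each, and none was called. The EC gate excluded kit on the surface, which germ cells carry. Kit transcripts were nonetheless 7.55 and 10.8 FPKM in EC against 8.79 and 10.9 in HE. The gate therefore does not decide for or against such cells. A difference between EC and HE themselves at this stage and site stays open as untested.

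Ribosomal pseudogenes were low in both E10.5 yolk sac libraries numbered 1, with mean log2 values of 1.51 and 1.81 against 2.88 to 3.82 elsewhere. A lower depth could not be decided by the share of named tested genes listed at 0. It was 1.09% in the lower of these libraries (HE replicate 1) and 1.52% in EC replicate 1, against up to 3.02% in another library (E10.5 yolk sac HE replicate 2). That other library had the highest relative depth, at 1.1, so the share at 0 did not follow depth. Relative depth was 0.97 for HE replicate 1, and EC replicate 1 had no clear step. A different treatment of reads that match several places is a candidate cause, as 37 pseudogenes of other genes were also lower, by −0.506 (SD 1.23) and −0.613, though the value only just passes the bound of −0.5 set for it. No biological explanation was tested.

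Other splits of the same libraries were compared with the real split by their number of calls, in models that keep the other factors as additive terms. The other splits leave the real factor out of the model, so its effect widens their spread and lowers their counts. Low counts there therefore do not exclude chance, nor a batch shared within a group. For HE against EC over all settings the real split gave 1318 genes and the others at most 2, with 1 of 100 splits reaching the real count. The real split also gave the most genes for yolk sac against embryo in HE (3565 against at most 1) and in EC (4064 against at most 1). So it did for stage in EC (25 against at most 2), each at 1 of 34 splits. For stage in HE the real split gave 2 genes and the others at most 1 (1 of 34), and for the interaction with site 9 against at most 8 (1 of 100). These leads of 1 gene each do not exclude chance, and they do not extend to the 318 and 15 genes of the fit by group. For the interaction with stage the splits decide nothing: limma called 0 genes in the real split, where 850 had an unadjusted p under 0.05, so that 100 of 100 splits gave at least as many, and the highest other gave 4. The split equal to the other factor of each model could not be fitted.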

How the results depend on the processing

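Chosen after the data were seen were the runs without both libraries labelled HE of the E10.5 yolk sac, without both E10.5 yolk sac libraries numbered 1, without genes listed at 0, and without unnamed models, pseudogenes and small RNA genes. The other alternatives were planned. Counts below are genes called by limma, and unless a cause is given, the cause was not tested.

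With 2 libraries in each group, counts within 1 stage and site depend on single libraries, and sort, litter and sequencing run cannot be separated from the groups. Of named genes called for HE against EC over all settings, 42 of 91 were called in all leave-one-out runs and 26 in every other setting. These numbers were 105 and 87 of 113 for yolk sac against embryo in HE, 108 and 110 of 111 for it in EC, 22 and 10 of 47 for stage in HE, and 6 and 21 of 37 for stage in EC. Within settings they were 2 and 0 of 7 in the E9.5 embryo, 0 and 0 of 1 in the E9.5 yolk sac, 0 and 0 of 9 in the E10.5 embryo and 3 and 1 of 73 in the E10.5 yolk sac. For the interactions they were 0 and 0 of 9 with site and 0 and 0 of 1 with stage.

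Treating the replicate number as a block moved the E9.5 yolk sac from 2 genes to 1 and the interaction with site from 15 to 46, and no other count by more than 1.5 times. The labels do not say whether replicate numbers pair the samples. The difference between replicates 1 and 2 correlated between groups at −0.26 to 0.38, above 0.1 in 8 of 28 pairs of groups. It was highest between EC and HE of the E9.5 yolk sac, and 0.2 and 0.15 between these and E9.5 embryo EC and 0.18 between EC and HE of the E10.5 yolk sac, so a day or run shared within some groups stays open.

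Without the libraries labelled HE of the E10.5 yolk sac, HE against EC over all settings gave 353 genes, 310 of them shared with the fit to all libraries. Yolk sac against embryo in HE gave 2122 (1982 shared), resting on E9.5 alone by construction. Stage in HE, resting on the embryo alone, gave 303 (133 shared), stage in EC 549 (282 shared) and the E9.5 embryo 35 (22 shared). The interaction with site, resting on E9.5, gave 0, with 696 genes at an unadjusted p under 0.05. Some effects reversed: Col1a1 in HE against EC over all settings (1.10), Col1a1 in the interaction with site (1.13) and Id1 with stage in HE (0.11). For Col1a1 the fitted fall came from its zeros in these libraries, by construction.

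Without both E10.5 yolk sac libraries numbered 1 the counts were 3036 for HE against EC over all settings, 1 in the E9.5 yolk sac, 1011 for stage in HE, 141 for the interaction with site and 46 with stage. Without unnamed models, pseudogenes and small RNA genes they were 1 in the E9.5 yolk sac, 39 for the interaction with site and 1 with stage. Leaving out genes listed at 0, leaving out small RNA genes and robust empirical Bayes moved no count by more than 1.5 times.

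A pseudocount of 0.1 gave 0 genes in the E9.5 yolk sac (1149 at an unadjusted p under 0.05), 5 in the E10.5 embryo, 148 and 149 for stage in HE and EC, and 7 and 1 for the interactions with site and stage. A pseudocount of 5 gave 39 in the E9.5 embryo, 44 in the E10.5 embryo, and 34 and 2 for these interactions. Without a filter there were 1065 genes for HE against EC over all settings, 58 and 11 in the E9.5 embryo and yolk sac, 94 in the E10.5 embryo, and 26 and 8 for the interactions. A filter at FPKM 5 gave 1 in the E9.5 yolk sac, 9 in the E10.5 embryo, 102 for stage in HE, 8 for the interaction with site and 0 with stage (625 at an unadjusted p under 0.05).

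Median-of-ratios scaling and quantile normalization each gave 1 gene in the E9.5 yolk sac. Scaling moved the balance of rises and falls: with median-of-ratios 52.6% of calls for site in HE were higher (39.7% as deposited), 72% for stage in HE and 68.7% for stage in EC (52.5% each as deposited). With quantile normalization these were 69.6% and 70.7% for stage in HE and EC, 22.2% in the E10.5 embryo (41.4%) and 42.1% for the interaction with site (26.7%). Without an intensity trend it had 4, and the interaction with site 28. Library quality weights gave 586 in the E9.5 embryo, 1 in the E9.5 yolk sac, 1 in the E10.5 yolk sac, 181 for stage in HE and 2 for the interaction with stage. With only the libraries of the groups compared there were 4 in the E9.5 embryo, 16 in the E10.5 embryo, 1 in the E10.5 yolk sac and 71 for stage in HE, with fewer libraries to estimate the spread by construction.

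With each library left out in turn, HE against EC over all settings ranged from 495 (E10.5 embryo EC replicate 1) to 2786 (E10.5 yolk sac HE replicate 1). Within settings the range was 5 (E9.5 embryo HE replicate 1) to 35 (E10.5 yolk sac HE replicate 1) in the E9.5 embryo. It was 0 (E9.5 yolk sac EC replicate 1, 652 at an unadjusted p under 0.05) to 3 (E10.5 embryo EC replicate 1) in the E9.5 yolk sac, 9 to 33 (E10.5 embryo EC replicates 1 and 2) in the E10.5 embryo, and 13 (E10.5 yolk sac EC replicate 1) to 2649 (HE replicate 1) in the E10.5 yolk sac, which gave 19 without HE replicate 2 and 470 without EC replicate 2. Yolk sac against embryo ranged from 3977 (E9.5 yolk sac HE replicate 2) to 5625 (E10.5 yolk sac HE replicate 1) in HE, and from 3345 (E9.5 embryo EC replicate 1) to 5229 (E10.5 yolk sac HE replicate 1) in EC. Stage ranged from 95 (E9.5 embryo HE replicate 1) to 853 (E10.5 yolk sac HE replicate 1) in HE, and from 39 (E9.5 embryo EC replicate 1) to 547 (E10.5 yolk sac HE replicate 2) in EC. The interaction with site ranged from 0 (E9.5 embryo EC replicate 1, 1395 at an unadjusted p under 0.05) to 395, and that with stage from 0 (E9.5 embryo EC replicate 2, 603 at an unadjusted p under 0.05) to 42, both highest without E10.5 yolk sac HE replicate 1.

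Called lists depend most on the correlation assumed within a list. With an estimated correlation camera called 0 lists in 9 comparisons and 1 in each comparison of stage. Lists at an unadjusted p under 0.05 then numbered 1 for HE against EC over all settings, 3 and 0 in the E9.5 embryo and yolk sac, 2 and 1 in the E10.5 embryo and yolk sac, 6 and 7 for site in HE and EC, and 6 and 2 for the interactions with site and stage. By fry the counts were 3 in the E9.5 embryo, 0 in the E9.5 yolk sac (3 at an unadjusted p under 0.05), 0 in the E10.5 embryo (8), 5 for stage in HE and 0 for the interaction with stage (2).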

Other observations

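All values here were looked up after the comparisons had been seen, and they carry no test beyond those already named.

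Libraries differed in how small RNA genes were listed. Of 39 tested small RNA genes, 82.1% stood at 0 in E10.5 yolk sac EC replicate 1, 74.4% in HE replicate 1 and 71.8% in HE replicate 2, against 28.2% to 53.8% in the other 13 libraries. Genes for ribosomal proteins took between 14% (E10.5 yolk sac HE replicate 2) and 27.9% (E10.5 embryo EC replicate 1) of the summed FPKM. The 10 most abundant genes took between 6.61% and 15.5%, the highest share in E9.5 yolk sac HE replicate 2.

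Among the genes called higher in HE of the E10.5 embryo, chosen after their values were seen, were Col5a3 (1.81), Cspg4 (1.30), Barx1 (1.28) and Myh11 (1.20), of which Myh11 and Cspg4 were low, at a mean of 1.89 and 1.91 FPKM in HE. In the libraries labelled HE of the E10.5 yolk sac, 4 of 16 fibrous matrix genes were called higher and 0 lower by limma, with a median of 1.37 (SD 0.369): Col5a2 (1.42), Col12a1 (1.96), Fbn1 (1.52) and the glycoprotein gene Tnc (2.12). Tnc was 158 and 143 FPKM there, 37.5 and 30.7 in EC of the same site and stage, and at most 39.7 in the other libraries.

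Some genes were listed at 0 in 1 or several libraries while no other library was near 0. Col1a1 was at 0 in both E10.5 yolk sac libraries labelled HE, and Igf2 was at 0 in replicate 2 and at 4552 FPKM in replicate 1 of the same group. Mest was at 0 in all 4 E9.5 embryo libraries and in E10.5 yolk sac EC replicate 2. With the 45 genes of this kind left out, no count of calls moved by more than 1.5 times.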
